A study of Rattus norvegicus with 16 samples.

How the data were processed

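The 16 arrays are Agilent 1-colour rat gene expression arrays on 2 slides, read with Feature Extraction 11.0.1.1 per the file headers. The design text of the series describes Illumina arrays and GenomeStudio, which the deposited files contradict, so the files were followed. Per the file headers, the deposited signal of each spot is an intensity on a linear scale, background-subtracted and detrended by the scanner software and not normalized between arrays. The deposited series matrix holds log2 values: each column has the same median of 7.91 and follows the log2 background-subtracted signal of its own array with a correlation across spots of at least 0.9991, as left by normalization between arrays by the authors, and 13.9% to 22.2% of its values are missing. Samples were grouped as the labels give them, in 8 groups of 2 arrays. Per the labels, tissue came from female rats, and cells were sorted with magnetic beads. No array had a saturated spot (0 on each), and the number of arrays limits the precision.

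Values were log2 of the processed signal minus the 75th percentile of the array. Spots marked as outliers by the scanner software were left out, replicate spots were averaged, and for each gene the probe with the highest mean over all arrays was used. Gene symbols came from matching the RefSeq accessions of the probes to a reference list of another genome build, used for names alone; 18355 of 30367 gene probes matched a symbol, and coordinates were not used. Genes well above background on every array of at least 1 group were tested, 18449 in all. All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), with a mean per group, and the 3 strata together with a term for the stratum. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, at least a 2-fold change, and signal well above background on every array of at least 1 compared group. Where the lower group was not well above background, the fold is written as "at least". For it, signals of that group below the lowest well-above-background signal of the array were raised to that signal. Where none was raised, it equals the estimated fold. It is not a confidence bound, so with sampling error the true fold may be smaller. The 12 comparisons were RT1B+ against RT1Blow in 3 strata, their differences between strains and between tissues and their common effect, WKY against LEW and glomeruli against blood in both populations, and RT1B+ cells against pan T cells and against the macrophage-labelled arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

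The comparisons, thresholds, gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. Up to 8 called genes with the largest rise and the largest fall were eligible to be named (4 for the RT1Blow comparisons of strains and tissues, the differences and the 3 strata), given a symbol and no overlap between the arrays of the groups. From each list described, up to 4 called members were eligible, and the label-check genes as well. Only some eligible genes are named. The 19 lists cover MHC class II and antigen presentation, NK cell receptors, cytotoxic granules and death ligands, T cells, macrophages, dendritic cells, B cells, neutrophils, mast cells, erythroid cells and platelets, glomerular cells, kidney tubule, cytokines, chemokines, chemokine receptors and trafficking, interferon response, cell cycle, immune checkpoints, and immediate early and heat shock genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The MHC class II list holds 2 genes of the gate used for sorting and the T cell list 1.

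The alternatives were another background correction (normexp with an offset of 50), quantile normalization, no filter or a stricter filter on dim probes, the series matrix values, the mean of all probes of a gene, no fold minimum, a trended and robust variance, fewer arrays in the fit, and each array left out in turn. For the 3 strata, pair means and slide 1 alone were tried too. The background correction was planned on mean spot signals; the files hold medians, which were used. The test was tested on simulated data with the spread of these arrays: for RT1B+ against RT1Blow in WKY blood, over 18449 genes, 82.1% of genes changed 4-fold and 91.0% of those changed 8-fold were recovered, with 4 false among 186 calls. For the same comparison in LEW blood the shares were 80.6% and 94.0% with 12 false among 194 calls, and in glomeruli 73.1% and 95.5% with 5 false among 183. Changes were placed only in genes well above background on every compared array, and the noise was normal and independent between genes. The real data gave 13, 11 and 118 calls in these comparisons, and more calls ease the adjusted threshold. These shares thus do not carry over to dimmer genes or to the real arrays. Spots on control positions were not analysed here.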

Results

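Gene expression was profiled on 16 Agilent 1-colour arrays hybridised with RNA from sorted leukocytes of female Wistar Kyoto (WKY) and Lewis (LEW) rats aged 15 weeks. Blood and kidneys were taken between days 30 and 35 after immunisation with an antigen that induces autoimmune glomerulonephritis. Cells were sorted with magnetic beads for CD8 and for RT1B, a rat MHC class II molecule, which gave CD8+ RT1B+ and CD8+ RT1Blow cells. Each was represented by 2 arrays from WKY blood, 2 from LEW blood and 2 from WKY glomeruli, and 2 further groups of 2 arrays were labelled WKY blood pan T cells and WKY glomerular macrophages. On each array 57.3% to 68.6% of 58717 gene spots were well above background, and 2 arrays per group limit the precision of every value below. The labels do not say whether the 2 arrays of a group came from different animals, so p-values measure the spread between arrays, which may be technical. In blood of both strains and in glomeruli, RT1Blow arrays lay in columns 1 and 2 of a slide and RT1B+ arrays in columns 3 and 4. Slide column and RT1B gate thus cannot be told apart. Levels are log2 signals relative to the 75th percentile of the array, and fold changes come with the standard error of the limma fit. For every gene said to rise or fall between 2 groups, each array of the higher group lay above each array of the lower group.

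Genes of natural killer (NK) cells used to check the labels, Klrb1a and Ncr1, were higher by group mean in each of the 6 CD8+ groups than in pan T cells. Klrb1a, the NK receptor NKR-P1A, stood at 2.98 ± 0.15 (SD, n = 2) in WKY blood RT1B+ cells, 2.96 ± 0.11 in WKY blood RT1Blow cells and 2.77 ± 0.30 in glomerular RT1B+ cells, against -0.54 ± 0.10 in pan T cells. Ncr1, the NK receptor NKp46, was at 2.53 ± 0.07 in WKY blood RT1B+ cells, 1.20 ± 0.90 in glomerular RT1Blow cells, 0.50 ± 0.46 in glomerular RT1B+ cells and -2.60 ± 1.43 in pan T cells. Cd8a lay between 3.07 and 4.47 in the 6 CD8+ groups and at 3.12 ± 0.50 in pan T cells, so it did not set these groups apart. Cd8b, the second chain of the CD8 heterodimer of most cytotoxic T cells, lay between -3.35 and -1.47 there and at 0.98 ± 0.62 in pan T cells. Cd3e, part of the T cell receptor complex, was at 2.41 ± 0.32 in pan T cells and between -2.81 and -0.70 in the CD8+ groups. The gated molecule itself was read by RT1-Bb, which was at 2.55 ± 0.57 against 1.15 ± 0.23 in WKY blood RT1B+ and RT1Blow cells. It was at 3.33 ± 0.16 against 1.48 ± 0.11 in LEW blood, and at 2.49 ± 0.07 against 2.36 ± 1.13 in glomeruli. The glomerular RT1Blow arrays read 1.56 and 3.16, so RT1Blow replicate 2 lay above both RT1B+ arrays (2.45 and 2.54), against its label. The probe for RT1-Ba was not well above background on any array, and Cd79a had no probe with that name.

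The 2 arrays labelled as glomerular macrophages carry an array name that reads pan T, so the label was set against marker genes. Cd14 was at 3.54 ± 0.32 and Cd68 at 3.90 ± 0.73 in these arrays, the highest of all 8 groups. Cd8a was at 0.59 ± 0.51 and Klrb1a at -0.62 ± 0.62. Cd3e was at -0.58 ± 0.78, below its 2.41 ± 0.32 in pan T cells but above its mean in each CD8+ group (-2.81 to -0.70). Csf1r, the receptor for macrophage colony-stimulating factor, was at -1.09 ± 0.27, below its level of -0.46 ± 0.60 in glomerular RT1Blow cells, and the scavenger receptor gene Cd163 was not well above background on either array. Kidney cell genes were high as well: the mean of the glomerular list was 0.15 and 0.72 and that of the tubule list -0.22 and -0.91 on these arrays, against at most -3.48 and -3.37 on any other. The arrays may hold more than macrophages.

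**Figure D1:**
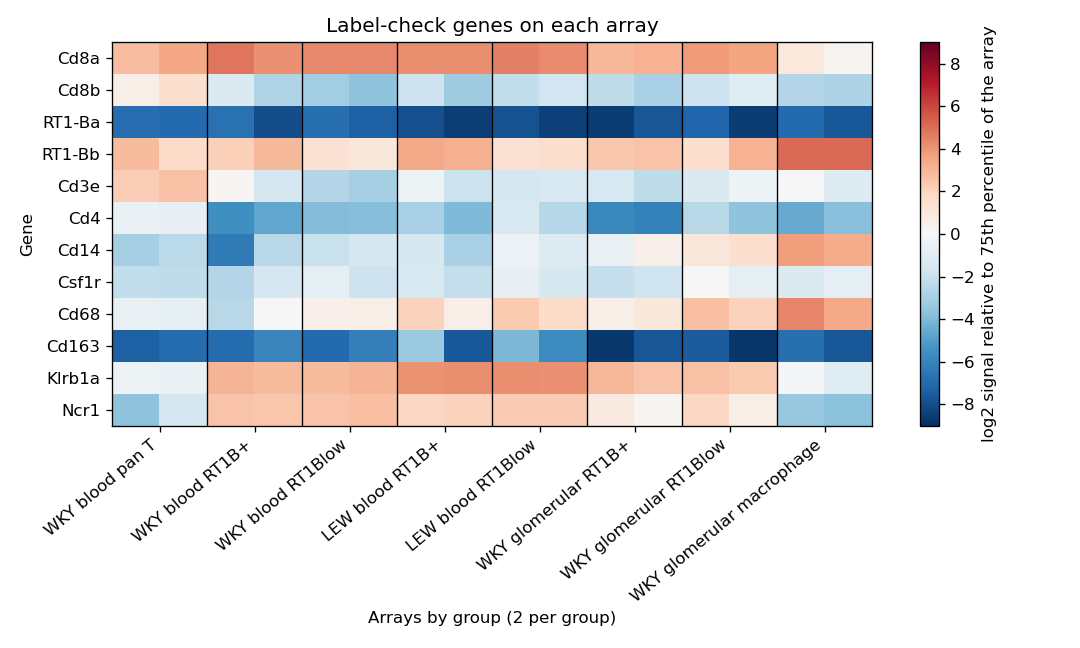
Levels of the label-check genes on each of the 16 arrays (log2 signal relative to the 75th percentile of the array, colour scale), with arrays in columns ordered by group. By group mean Klrb1a lay between 2.50 and 4.13 in the 6 CD8+ groups and at -0.54 and -0.62 in pan T and macrophage-labelled arrays, and Ncr1 between 0.50 and 2.64, against -2.60 and -3.54.

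Against pan T cells, WKY blood RT1B+ cells had more NK and cytotoxic gene transcript and less T cell transcript. Of 23 tested NK genes, 19 rose, and 19 when adjusted over the list alone. Ncr1 rose 34.9-fold (log2 5.13 ± 0.56, adjusted p = 7.87e-05), the low-affinity IgG receptor gene Fcgr3a 33.5-fold and the lectin-like receptor genes Klri1 and Klri2 by 19.6-fold and 12.9-fold. Of 19 granule and death ligand genes 11 rose (11 adjusted over the list alone), among them the granzyme genes Gzmb (27.7-fold), Gzmc (26.0-fold) and Gzma (20.6-fold). Of 21 T cell markers 14 fell and 1 rose (14 and 1 adjusted over the list alone): Lef1, a transcription factor of naive T cells, fell 163-fold (log2 -7.35 ± 0.47), the interleukin 7 receptor gene Il7r 128-fold, Cd5 27.3-fold and Cd4 21.8-fold, where Il7r and Cd4 were well above background on 1 of the 2 RT1B+ arrays. Killer lectin-like receptor, granzyme and RT1 genes belong to families of similar sequence, so which member a probe reads is uncertain here and below.

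Genes of dividing and of recently activated cells were also higher in the RT1B+ cells than in pan T cells. Of 29 cell cycle genes 24 rose and none fell (24 adjusted over the list alone), with Tpx2 (well above background on 1 of the 2 pan T arrays) at 8.66-fold, Bub1 at 8.57-fold and Cdk1 at 8.13-fold. Of 28 immediate early and heat shock genes 18 rose and 1 fell (19 and 1 adjusted over the list alone), with Nr4a1 at 36.8-fold, Fosl2 at 29.2-fold and Nr4a2 at 25.6-fold. Genes of other cell types moved as well: 11 of 17 B cell markers rose and 1 fell (11 and 1 adjusted over the list alone), with Cd79b, a B cell receptor component, at 8.45-fold, and 6 of 12 erythroid and platelet genes fell (7 adjusted over the list alone), with Alas2, the erythroid haem synthesis enzyme, 143-fold lower. Xcl1, Ccl3 and Ccl4, chemokines released by NK and T cells, were 26.0-fold, 11.2-fold and 8.84-fold higher, and the lymph node homing receptor gene Ccr7 was 54.3-fold lower. Camera called the NK (adjusted p = 2.69e-14), granule (adjusted p = 2.21e-08), T cell (adjusted p = 5.24e-09), cell cycle (adjusted p = 3.58e-15), immediate early (adjusted p = 8.66e-13), B cell (adjusted p = 2.31e-06) and erythroid (adjusted p = 0.000475) lists. With an estimated correlation none was called, at adjusted p = 0.0624, 0.0925, 0.0925, 0.0925, 0.0876, 0.0624 and 0.439 in that order. In all, 3097 of 18449 genes passed the test, 1658 higher and 1439 lower in RT1B+ cells, and 1743 when only these 4 arrays were fitted. The 2 groups were hybridised on different slides, so slide and cell population cannot be told apart here.

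In WKY blood, RT1B+ cells exceeded RT1Blow cells in MHC class II and B cell transcripts. Ciita, the master regulator of MHC class II transcription, was at least 3.94-fold higher (adjusted p = 0.0460) and was not well above background in RT1Blow cells. Blk, a B cell tyrosine kinase, was at least 5.94-fold higher (adjusted p = 0.0368), and Mzb1, a plasma cell and marginal zone B cell protein gene, was 5.82-fold higher (log2 2.54 ± 0.38, adjusted p = 0.0491), though well above background on only 1 of the 2 RT1Blow arrays. Of 15 MHC class II and antigen presentation genes 1 passed the test and 8 adjusted over the list alone, all higher, and the list had a median log2 change of 1.09 (camera adjusted p = 1.54e-10, adjusted p = 0.0945 with an estimated correlation). Of 17 B cell genes 2 passed and 10 adjusted over the list alone, all higher, with a median of 1.44 (camera adjusted p = 1.05e-21, adjusted p = 0.00136 with an estimated correlation). The erythroid and platelet list had a median of -2.64 (camera adjusted p = 1.62e-11, adjusted p = 0.0945 with an estimated correlation) with 0 of 12 members passing and 6 adjusted over the list alone. The macrophage list had a median of -1.17 (camera adjusted p = 1.85e-08, adjusted p = 0.260 with an estimated correlation) with none of 26 passing. By array, the mean of that list was -3.27 and -1.64 in RT1B+ and -1.34 and -1.10 in RT1Blow cells, so much of the difference came from RT1B+ replicate 1. T cell markers had a median of 0.41 (camera adjusted p = 3.87e-06, adjusted p = 0.210 with an estimated correlation), with 0 of 21 passing and 4 higher adjusted over the list alone. Cd3e had a log2 difference of 2.11 ± 0.63 (adjusted p = 0.515). Mast cell and basophil markers had a median of -0.97 (camera adjusted p = 1.37e-07, adjusted p = 0.0945 with an estimated correlation), with 0 of 12 passing and 2 lower adjusted over the list alone. Camera called chemokine (median -0.81, 0 of 21 passing, adjusted p = 0.000173), cytokine (median -0.38, 0 of 25, adjusted p = 0.00710), neutrophil (median -0.60, 0 of 10, 1 lower adjusted over the list alone, adjusted p = 0.0328) and glomerular genes (median -0.28, 0 of 20, adjusted p = 0.0328) lower. It called cell cycle genes (median 0.37, 0 of 29, adjusted p = 7.08e-10) higher. None of these 5 calls held with an estimated correlation (adjusted p = 0.258, 0.295, 0.268, 0.447 and 0.210). Of NK and granule genes 0 of 23 and 0 of 19 passed, with medians of -0.10 and -0.04. Since only 13 of 18449 genes passed in this comparison, these counts do not show that the 2 lists were equal.

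Beyond these lists, the mRNA editing enzyme family gene Apobec2 was at least 6.49-fold and the transporter gene Slc15a5 at least 4.46-fold higher in WKY blood RT1B+ cells, and Rspo2, which encodes a Wnt pathway agonist, was at least 3.16-fold lower. The pseudogene Hmgb1-ps2, whose probe may pick up related transcripts and is uncertain for that reason, was at least 26.2-fold lower. Altogether 13 genes passed, 6 higher and 7 lower, against 0 of 18449 when only the 4 arrays, or only the 8 arrays of the slide, were fitted. Without WKY blood RT1B+ replicate 1 or 2, or RT1Blow replicate 1 or 2, the counts were 0, 34, 5 and 48, and 0 of the 7 genes named here stayed called in each of these 4 fits.

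LEW blood gave the same 2 gene groups on the RT1B+ side and red cell genes on the other. Fcmr, the IgM Fc receptor gene of B cells, was 7.25-fold higher in RT1B+ cells (log2 2.86 ± 0.40, adjusted p = 0.0345), Blk 6.54-fold and RT1-DOb, a class II chaperone chain of B cells, 4.14-fold. The largest differences were lower: Alas2 fell 466-fold (log2 -8.86 ± 1.28, adjusted p = 0.0390), and the haemoglobin genes Hbb-bs, Hbb-b1 and Hba-a1 fell 343-fold, 145-fold and 56.2-fold. Haemoglobin genes share sequence, so their probes cannot be assigned to single genes with certainty, and the 2 Hba-a1 probes read log2 changes of -8.59 and -5.81. Of 15 MHC class II genes 1 passed and 6 adjusted over the list alone, all higher (median 0.96, camera adjusted p = 5.44e-11, adjusted p = 0.0752 with an estimated correlation). Of 17 B cell genes 1 passed and 13 adjusted over the list alone, all higher (median 2.18, camera adjusted p = 2.69e-37, adjusted p = 0.000183 with an estimated correlation). Erythroid genes (median -4.78, 3 of 12 lower, 9 adjusted over the list alone) and mast cell genes (median -1.36, 0 of 12, 5 lower adjusted over the list alone) were called lower by camera, both with adjusted p = 0.0174 with an estimated correlation. Camera also called macrophage genes (median -0.68, 0 of 26 passing, adjusted p = 0.000731) and chemokine genes (median -0.43, 0 of 21, adjusted p = 0.000827) lower, but not with an estimated correlation (adjusted p = 0.730 and 0.454). By array, the mean of the macrophage list was 0.03 and -1.98 in RT1B+ and 0.14 and -0.58 in RT1Blow cells. RT1B+ replicate 1 thus lay above RT1Blow replicate 2, and the lower value rests on RT1B+ replicate 2. Altogether 11 genes passed, 7 higher and 4 lower, and 0 did so with only the 8 arrays of the slide, with the series matrix values or with no filter on dim probes. Without LEW RT1B+ replicate 1 or 2, or RT1Blow replicate 1 or 2, the counts were 16, 8, 0 and 2, and 0 of the 7 genes named stayed called in each. The 16 genes were all lower and shared 0 with the 11, and the 5 called with only the 4 arrays were all lower too.

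In glomeruli the RT1B+ cells did not exceed the RT1Blow cells in MHC class II transcripts, and genes of several other cell types were lower. Of 15 MHC class II genes none passed (2 lower adjusted over the list alone), with a median of -0.71 (camera adjusted p = 0.00309, adjusted p = 0.494 with an estimated correlation). Of 17 B cell genes 5 fell (8 adjusted over the list alone, with 1 higher): Spib, a B cell and plasmacytoid dendritic cell transcription factor, 16.5-fold (log2 -4.04 ± 0.54, adjusted p = 0.0133), Cd79b 9.39-fold and Blnk 8.44-fold, while Fcmr, outside the list, fell 16.5-fold. The haemoglobin genes Hbb, Hbb-b1 and Hba-a1 fell 51.4-fold, 48.8-fold and 29.5-fold. Umod, the uromodulin gene of the thick ascending limb, fell 5.44-fold, the inhibitory Fc receptor gene Fcgr2b 3.08-fold, Cd4 7.59-fold and the interleukin gene Il22 3.96-fold. Cd79b, Cd4 and Il22 were well above background on 1 of the 2 RT1B+ arrays. The other probe for Fcgr2b read a log2 change of -0.78 against -1.63. List medians were -1.63 for B cell genes (camera adjusted p = 5.47e-07), -1.68 for neutrophil genes (adjusted p = 0.000969), -1.60 for kidney tubule genes (adjusted p = 0.00105) and -1.43 for macrophage genes (adjusted p = 0.000682). With an estimated correlation none of these calls held, at adjusted p = 0.0654, 0.276, 0.345 and 0.517. Erythroid genes (median -1.67, 3 of 12 lower, 5 adjusted over the list alone, camera adjusted p = 0.000633) and mast cell genes (median -0.98, 0 of 12, 3 lower adjusted over the list alone, camera adjusted p = 0.00624) were both at adjusted p = 0.471 with an estimated correlation. Chemokine genes (median -0.73, 0 of 21, 4 lower adjusted over the list alone, camera adjusted p = 0.0312) and interferon response genes (median -0.46, 0 of 27, 2 lower adjusted over the list alone, camera adjusted p = 0.00673) were both at 0.517.

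On the RT1B+ side of the glomerular comparison, Cavin3, a caveolar coat protein gene, rose 4.37-fold (log2 2.13 ± 0.36, adjusted p = 0.0357), Dclk1 4.06-fold, Thoc1, an mRNA export factor gene, 2.91-fold, and the histone chaperone gene Supt16h 2.82-fold. None of 29 cell cycle genes passed, with a list median of 0.61 (camera adjusted p = 9.01e-09, adjusted p = 0.345 with an estimated correlation), and the median over all genes was -0.15. Of 18449 genes 118 passed, 30 higher and 88 lower. The share that was higher, 25.4%, was 45.3% of 75 genes with quantile normalization, 41.7% of 103 after another background correction and 35.7% of 28 with the series matrix values. Only 6 genes passed with the 8 arrays of the slide alone and 0 with the 4 arrays alone, and without RT1B+ replicate 1 or 2, or RT1Blow replicate 1 or 2, the counts were 13, 9, 13 and 669, with 1 of the 15 genes named called in each.

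**Figure D2:**
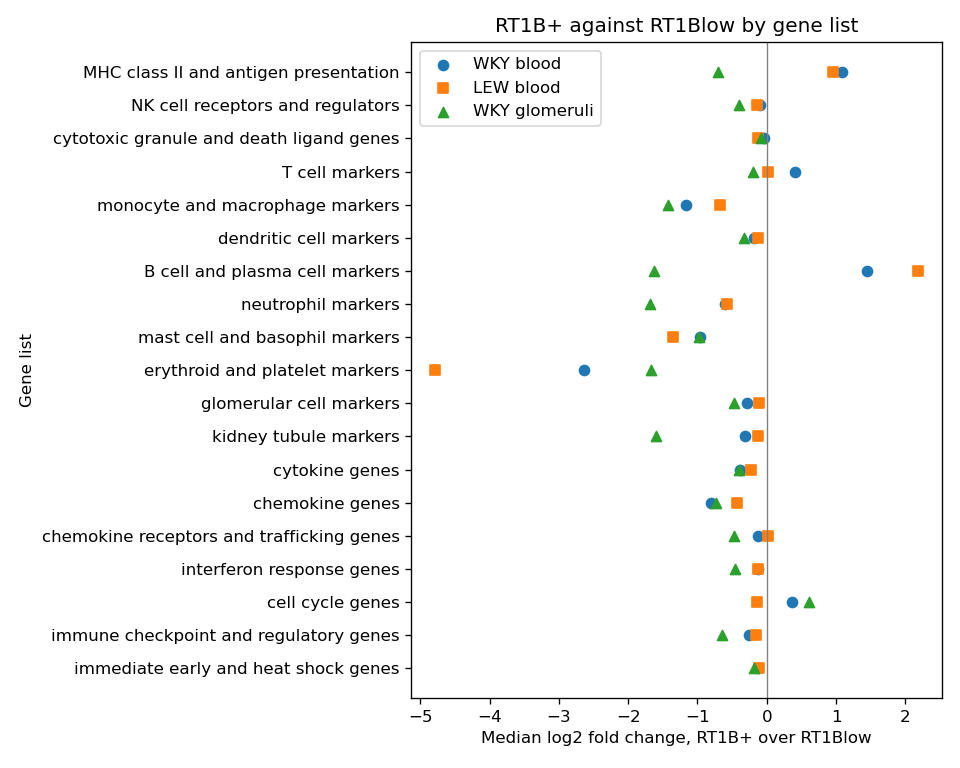
Median log2 fold change of RT1B+ over RT1Blow cells (horizontal axis, dots) for each of the 19 gene lists (vertical axis) in WKY blood, LEW blood and WKY glomeruli. The B cell list lay at 1.44 and 2.18 in blood and at -1.63 in glomeruli, and the erythroid list was below 0 in all 3.

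The RT1B-associated differences were compared between strains and tissues by their interaction. B cell genes set glomeruli apart from blood: Fcmr (log2 difference of differences -6.24 ± 0.56, adjusted p = 0.00132), Spib (-6.01 ± 0.77), Cd79b (-5.76 ± 0.73), Pou2af1 (-4.56 ± 0.67) and Blk (-4.47, not exact because Blk was not well above background in WKY blood RT1Blow cells) were called, as was Srpk3 (-5.29 ± 0.65), a serine and arginine kinase gene. Of 17 B cell genes 6 passed and 11 adjusted over the list alone, all negative (median -3.45, camera adjusted p = 1.23e-21, adjusted p = 0.00138 with an estimated correlation). The MHC class II list had a median of -1.37 with 0 of 15 passing and 7 adjusted over the list alone (camera adjusted p = 4.92e-11, adjusted p = 0.139 with an estimated correlation). Altogether 19 genes differed between glomeruli and blood, all more negative in glomeruli, against 3 when only the 8 arrays were fitted and 10 of 29 positive with quantile normalization. Without glomerular RT1B+ replicate 1 or 2 the count was 7 and 11, and without glomerular RT1Blow replicate 2 it was 39, and 2 of the 6 genes named stayed called without any 1 array. Between WKY and LEW blood no gene passed in limma, with 242 at an unadjusted p under 0.05, and 0 with a trended and robust variance. Quantile normalization gave 4.

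Over the 3 strata together, red cell and mast cell genes were lower in RT1B+ cells. In the fit with a stratum term, Hbe2 was 95.8-fold lower (log2 -6.58 ± 0.87, adjusted p = 0.0265), Alas2 71.7-fold and Hbb-bs 68.2-fold, and Hba-a3 fell too. Of 12 erythroid and platelet genes 4 fell (10 adjusted over the list alone), and the mast cell protease genes Cma1 and Mcpt1 fell. No fold is given for Hba-a3, Cma1 and Mcpt1, which were not well above background in at least 2 of the 3 RT1B+ groups. Alas2 was well above background on 1 of the 2 glomerular RT1B+ arrays. Cavin3 was the 1 gene that rose, by 3.35-fold (log2 1.74 ± 0.23, adjusted p = 0.0265), though well above background on 1 of the 2 RT1Blow arrays in each strain's blood, and the chemokine gene Cxcl10 fell 2.43-fold. The erythroid list had a median of -3.38 (camera adjusted p = 1.8e-12, adjusted p = 0.122 with an estimated correlation), and the mast cell list was called lower too (adjusted p = 9e-10, adjusted p = 0.122 with an estimated correlation). RT1-Bb had a log2 difference of 1.13 ± 0.33 (adjusted p = 0.165). In all 18 genes passed, 1 higher and 17 lower, and 2 did when the arrays of each group were averaged first. The 2 strata of slide 1 alone gave 60, of which 51 were higher, while 0 of the 8 called genes named stayed called without any 1 array. The count was 0 without WKY blood RT1B+ replicate 2, WKY blood RT1Blow replicate 1, LEW blood RT1Blow replicate 1 or 2, or glomerular RT1B+ replicate 2. It was 9 without WKY blood RT1B+ replicate 1, 8 without LEW RT1B+ replicate 2, 5 without glomerular RT1B+ replicate 1 and 43 without LEW RT1B+ replicate 1.

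WKY and LEW blood RT1B+ cells differed most in a small set of genes with large changes. Cpne4, a calcium-dependent phospholipid-binding protein gene, was at least 297-fold lower in WKY (adjusted p = 0.000845), Trpv4, a cation channel gene, 154-fold lower (log2 -7.27 ± 0.91, adjusted p = 0.00650), Cacnb4, a calcium channel subunit gene, 40.8-fold and B3galnt1 at least 19.5-fold lower. Slc27a2, a fatty acid transport protein gene, was 132-fold higher in WKY (log2 7.04 ± 1.12, adjusted p = 0.0183), the embryonic globin gene Hbe1 at least 43.6-fold, Cp, the ceruloplasmin gene, 18.2-fold and Farp1 10.5-fold higher. The other probe for Farp1 read a log2 difference of 0.40 against 3.39, and that for Cpne4 -7.03 against -8.79. Trpv4, B3galnt1, Slc27a2 and Hbe1 had no other probe. Of 15 MHC class II genes 2 fell in WKY relative to LEW (2 adjusted over the list alone), Ciita and RT1-DOb, both 2.90-fold (median -1.05, camera adjusted p = 3.73e-08, adjusted p = 0.286 with an estimated correlation). B cell genes had a median of -0.61 there, with 0 of 17 passing and 3 lower adjusted over the list alone (camera adjusted p = 0.00234, adjusted p = 0.286 with an estimated correlation). Ebi3, a subunit of interleukins 27 and 35, was 6.08-fold lower and the NK receptor gene Klri2 3.38-fold lower. Macrophage genes had a median of -1.42 with none of 26 passing and 7 lower adjusted over the list alone (camera adjusted p = 1.41e-08, adjusted p = 0.406 with an estimated correlation). By array, the mean of that list was -3.27 and -1.64 in WKY and 0.03 and -1.98 in LEW. WKY replicate 2 thus lay above LEW replicate 2, so the strains overlapped. In all 118 genes passed, 44 higher and 74 lower in WKY, and 16.8% of 125 were higher with the series matrix values, which shift the median over all genes to -0.32, against 37.3%. The count was 2, both higher, with only the 4 arrays and 289 with only the slide, and without WKY replicate 1 or LEW replicate 1 it was 32 and 18, with 4 of the 12 genes named called without any 1 array. The strains lay in different rows of the slide.

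The RT1Blow cells of the 2 strains differed in many of the same genes. Cpne4 was at least 181-fold lower in WKY, Trpv4 136-fold (well above background on 1 of the 2 WKY arrays) and B3galnt1 at least 16.3-fold, while Slc27a2 was 120-fold higher (log2 6.90 ± 1.12, adjusted p = 0.0171) and Acod1, the itaconate-producing enzyme gene of myeloid cells, at least 48.3-fold higher. Lef1 was 6.56-fold lower (well above background on 1 of the 2 WKY arrays, with a log2 difference of -1.37 against -2.71 by its other probe), Ciita at least 4.18-fold and Klri2 4.14-fold lower, and the NK receptor gene Klra2 was 4.83-fold higher. Of the 44 and 79 genes higher in WKY in RT1B+ and RT1Blow cells 35 were shared, and of the 74 and 92 lower genes 45, where independent lists would share 0.188 and 0.369. The 2 comparisons share no array, but they use the same spread per gene and set the same slide rows apart. Their lists are thus not independent, and the overlap does not replicate a strain difference. Altogether 171 genes passed, 79 higher and 92 lower, and 12.1% of 331 were higher with the series matrix values, which shift the median over all genes to -0.32, against 46.2%. The count ran from 48 with another background correction to 477 with only the 4 arrays, and without WKY replicate 1 or 2, or LEW replicate 1 or 2, it was 59, 71, 27 and 12, with 1 of the 9 genes named called in each.

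**Figure D3:**
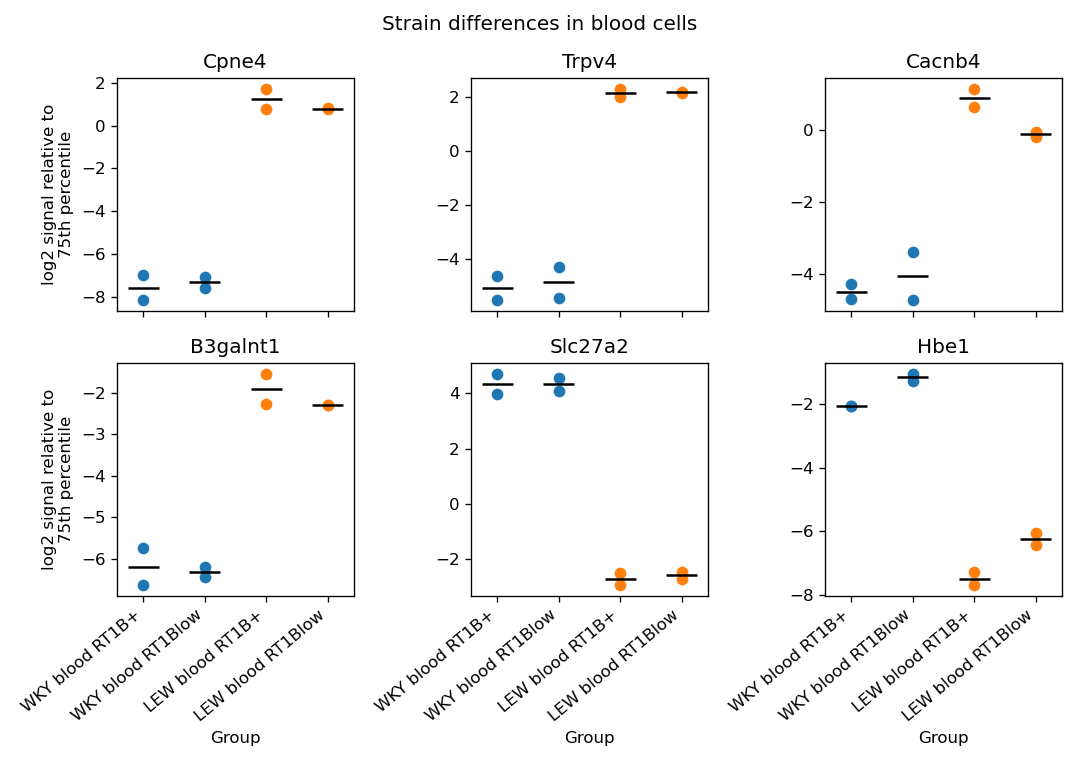
Levels of 6 genes on each array of the 4 blood CD8+ groups (vertical axis, log2 signal relative to the 75th percentile of the array), each point being 1 array and each bar the mean of 2. Cpne4, Trpv4, Cacnb4 and B3galnt1 were lower and Slc27a2 and Hbe1 higher in WKY than in LEW in both populations.

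Glomerular RT1B+ cells differed from blood RT1B+ cells of the same strain in cytokine, chemokine and B cell genes. Ccl1, a chemokine of activated lymphocytes, was 914-fold higher in glomeruli (log2 9.84 ± 0.48, adjusted p = 3.03e-06) though well above background on only 1 of the 2 blood arrays, Cavin3 was 183-fold higher, and the costimulatory receptor genes Tnfrsf9 and Crtam were 143-fold and 138-fold higher. Of 25 cytokine genes 11 rose and 2 fell (13 and 3 adjusted over the list alone), among them Il1a (at least 57.4-fold), Il1rn (21.2-fold) and Lta (20.6-fold); the other probe for Il1a read a log2 change of 2.73 against 5.84. Of 21 chemokine genes 9 rose (9 adjusted over the list alone), among them Ccl7 (13.5-fold) and Cx3cl1 (11.7-fold). Of 25 checkpoint and regulatory genes 10 rose and 1 fell (11 and 2 adjusted over the list alone), among them Il2ra (24.3-fold), and camera did not call that list (adjusted p = 0.0518, adjusted p = 0.737 with an estimated correlation). Of 19 granule and death ligand genes 3 rose, Gzmf (16.1-fold), Fas (5.20-fold) and Tnfsf10 (at least 4.44-fold), and Gzmk fell 2.32-fold (4 and 1 adjusted over the list alone). Camera did not call that list (adjusted p = 0.234), and its median of 0.35 was -0.06 with the series matrix values, where its direction turned. Of 23 NK genes Klra2 rose 6.49-fold, and Ncr1 and Klrd1 fell 4.09-fold and 2.32-fold (1 and 2 adjusted over the list alone, camera adjusted p = 0.153). With an estimated correlation both lists were at adjusted p = 0.737. Gzmf, Ccl7, Cx3cl1 and Il2ra were well above background on 1 of the 2 blood arrays. The other probe for Fas read a log2 change of 1.61 against 2.38.

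B cell genes were lower in glomerular than in blood RT1B+ cells: of 17, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with Fcmr 63.1-fold lower (log2 -5.98 ± 0.40, adjusted p = 2.02e-05), and Spib 35.0-fold lower (median -2.64, camera adjusted p = 1.27e-10, adjusted p = 0.0159 with an estimated correlation). Several genes known from macrophages and kidney cells rose: Gpnmb 195-fold, with 1 of 2 blood arrays well above background, Lgals3 31.8-fold, Mmp12 at least 178-fold, Spp1 at least 158-fold, the podocyte and endothelial gene Podxl at least 26.9-fold and the proximal tubule gene Ass1 at least 83.9-fold. Of 26 macrophage genes 6 rose and 2 fell (8 and 2 adjusted over the list alone), of 20 glomerular genes 6 rose (7 adjusted over the list alone), and of 15 tubule genes 2 rose and 1 fell (2 and 1 adjusted over the list alone). Camera called none of these 3 lists (adjusted p = 0.178, 0.126 and 0.412, each 0.737 with an estimated correlation). The MHC class II list had a median of 0.08 with 1 gene higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.658, adjusted p = 0.814 with an estimated correlation). Camera called the cytokine (adjusted p = 0.0062) and chemokine (adjusted p = 0.0135) lists higher, both at adjusted p = 0.737 with an estimated correlation. In all 2435 genes passed, 1485 higher and 950 lower, or 61.0% higher against 78.9% of 2263 with the series matrix values, with medians over all genes of 0.10 and 0.29. The count was 687 with only the 4 arrays and 1026 without glomerular RT1B+ replicate 2, with 21 of the 25 genes named called without any 1 array. The tissues lay on different slides, so slide and tissue cannot be told apart.

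In RT1Blow cells, cytokine and MHC class II genes were higher in glomeruli than in blood. Ccl1 rose 185-fold (log2 7.53 ± 0.48, adjusted p = 5.43e-05) and Gpnmb 121-fold. Of 15 MHC class II genes 9 rose (11 adjusted over the list alone), among them Cd40 (7.45-fold), Ciita (at least 5.95-fold) and Cd86 (4.63-fold), with a median of 1.65 (camera adjusted p = 7.09e-06, adjusted p = 0.451 with an estimated correlation). Of 25 cytokine genes 8 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.451 with an estimated correlation), among them Il1a (at least 65.5-fold), Il17a (25.6-fold) and Tnf (9.76-fold). The other probe for Il1a read a log2 change of 3.94 against 6.03. Markers of other cells moved too: of 13 dendritic cell genes 5 rose (5 higher and 1 lower adjusted over the list alone, median 1.07, camera adjusted p = 0.0233, adjusted p = 0.451 with an estimated correlation). Of 26 macrophage genes 3 rose (5 adjusted over the list alone, median 1.06) and of 21 T cell genes 7 (8 adjusted over the list alone, median 0.68), and camera did not call these 2 lists (adjusted p = 0.0559 and 0.149, both 0.794 with an estimated correlation). The alarmin genes S100a9 and S100a8, abundant in neutrophils, rose 32.4-fold and 12.5-fold. The tubule genes Ass1 and Umod rose 35.2-fold and at least 10.2-fold, 4 of 15 tubule genes rising (6 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.451 with an estimated correlation). S100a9, S100a8, Ass1 and Il17a were well above background on 1 of the 2 blood arrays. Of 23 NK genes none passed, with a median of -0.17. Of the 1485 and 1160 genes higher in glomeruli in RT1B+ and RT1Blow cells 669 were shared, against 93.4 for independent lists, and of the 950 and 547 lower genes 336, against 28.2. These lists are not independent, because both comparisons use the same spread per gene and set the same slides apart. In all 1707 genes passed, 1160 higher and 547 lower, a share of 68.0% against 80.9% with the series matrix values and 55.8% with quantile normalization, where the median over all genes was 0.16, 0.26 and 0.00 in that order. The count was 17 with only the 4 arrays and 954 with no filter on dim probes, and without glomerular replicate 1 or 2, or blood replicate 1 or 2, it was 819, 928, 757 and 299, with 9 of the 12 genes named called in each. Slide and tissue cannot be told apart.

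Glomerular RT1B+ cells and the macrophage-labelled arrays differed in NK, macrophage and kidney cell genes. Of 23 NK genes 22 rose in RT1B+ cells (22 adjusted over the list alone). Among them were Ncr1 (16.5-fold, log2 4.04 ± 0.56, adjusted p = 0.000194) and Klrb1c (12.1-fold). In the same arrays 14 of 19 granule genes rose (14 adjusted over the list alone), among them Gzma (12.3-fold), Gzmk (9.93-fold) and Prf1 (7.84-fold), the perforin gene. Crtam was 23.3-fold and Tp73, a p53 family gene, 19.1-fold higher. Of 26 macrophage genes 20 fell (20 adjusted over the list alone), among them the endotoxin receptor gene Tlr4 (30.1-fold), Msr1 (15.0-fold) and Cd14 (12.1-fold). Of 15 MHC class II genes 14 fell (14 adjusted over the list alone), among them Cd40 (16.6-fold) and RT1-Da (8.71-fold). Genes of resident kidney cells fell further: 18 of 20 glomerular genes fell and 1 rose (18 and 1 adjusted over the list alone), with Col4a1 201-fold, Sparc 195-fold, Emcn 163-fold and Podxl 150-fold lower. Of 15 tubule genes 14 fell (14 adjusted over the list alone), with Miox 120-fold and Slc34a1 at least 111-fold lower. Of 10 neutrophil genes 8 fell (8 adjusted over the list alone), with Lcn2 42.5-fold lower. The chemokine genes Cx3cl1, Cxcl11 and Cxcl9 were 114-fold, 67.2-fold and 60.4-fold lower. Of 13 dendritic cell genes 8 fell and 3 rose (8 and 3 adjusted over the list alone). Of 27 interferon response genes 12 fell and 2 rose (12 and 2 adjusted over the list alone). Of 23 chemokine receptor and trafficking genes 5 fell and 8 rose (5 and 8 adjusted over the list alone). The other probe for Col4a1 read a log2 change of -4.13 against -7.65. Tlr4, Msr1, Lcn2 and Miox were well above background on 1 of the 2 RT1B+ arrays.

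Camera called the NK (adjusted p = 1.72e-08), macrophage (adjusted p = 4.15e-07), MHC class II (adjusted p = 1.25e-08), glomerular (adjusted p = 3.84e-10), tubule (adjusted p = 1.05e-08) and neutrophil (adjusted p = 1.05e-05) lists in the comparison with macrophage-labelled arrays. With an estimated correlation none was called, at adjusted p = 0.104, 0.215, 0.104, 0.0614, 0.0614 and 0.0614 in that order. The granule (adjusted p = 0.000145), dendritic cell (adjusted p = 0.00457) and interferon response (adjusted p = 1.28e-05) lists lost their calls too, at adjusted p = 0.213, 0.203 and 0.213 with an estimated correlation. The chemokine receptor list was not called (adjusted p = 0.987), its camera direction turning with the other background correction. Of 18449 genes 6727 passed, 3770 higher and 2957 lower in RT1B+ cells, or 56.0% higher against 66.9% with the series matrix values and 49.8% of 7186 with no filter on dim probes. The median over all genes was shifted by 0.33 on the log2 scale (0.31 with quantile normalization and 0.50 with the series matrix values), and 4316 genes passed among those well above background on all 16 arrays, 3165 higher and 1151 lower, or 73.3% higher. Without any 1 array, 20 of the 22 genes named stayed called.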

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

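The tests of cell sources, scaling, a divergent array, other probes and slide rows were chosen, or had related values in view, only after the result was seen; the count of splits was set before.

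The effect of the RT1B gate differed between glomeruli and blood of WKY rats by a test of the difference itself, in 19 genes. Fcmr (-6.24), Spib (-6.01), Cd79b (-5.76), Srpk3 (-5.29), Pou2af1 (-4.56) and Blk (-4.47, not exact because WKY blood RT1Blow cells were not well above background) were named among them, and the B cell list had a median difference of -3.45 on the log2 scale.

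In blood, B cell and MHC class II genes were higher together in RT1B+ arrays of both strains. The medians of the class II list lay between 0.97 and 1.14 under 2 other scalings in both strains. These values cannot decide on scaling between arrays as a cause, because the other scalings lay close to the one used. The median over all genes was -0.06 in WKY with the scaling used, and 0.02 and 0.01 with the others. In LEW it was -0.07, and 0.03 with both others. Camera also called the list at the preset correlation in 4 of 4 cases. Those calls cannot test scaling, because camera sets a list against all other genes and a shift of all genes alike cancels. With an estimated correlation camera did not call the list in either strain (adjusted p = 0.0945 in WKY and 0.0752 in LEW). B cells passing the RT1B gate stay open, although the cells were also sorted for CD8: that 16 of 17 B cell genes were higher in both strains restates the pattern and cannot decide it. The median log2 strain ratio of the class II gain differed from that of the B cell gain by 0.04, which leaves open that B cells are its whole source. The SE of 0.44 set beside it is that of a difference of means over genes. Genes are not independent replicates, so it does not measure the spread between animals. The strain ratio used only genes that gained in both strains, 10 of 15 class II and 16 of 17 B cell genes. It says nothing of the genes left out. Class II expression by the RT1B+ cells themselves cannot be told apart from this, because in glomeruli, where the class II list had a median of -0.71, macrophage genes were lower too, at -1.43.

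In glomeruli, markers of 8 of 8 other cell types had medians below 0 in RT1B+ relative to RT1Blow arrays, from -1.68 to -0.33, but so had 10 of the 11 remaining lists, and the median over all genes was -0.15, so the direction alone is not particular to other cell types. More cells of other types in RT1Blow arrays stays open: by the criterion first set, the range of the medians, 1.35, counted against it beside a spread of 1.25 between genes of a list. Single genes vary more than medians, so that comparison cannot show whether the lists moved apart, and the reading was changed after the value was seen. For the list means, a single divergent RT1Blow array was argued against, with both RT1Blow arrays above both RT1B+ arrays in 8 of 8 lists. For dendritic cell genes the margin was small (-1.27 against -1.30). This covers list means alone, since RT1-Bb on RT1Blow replicate 2 (3.16) lay above both RT1B+ arrays (2.45 and 2.54). Scaling was not decided, although 7 of 8 medians stayed below 0 after quantile normalization. That step moved the median over all genes only from -0.15 to 0.02, so medians far below 0 could hardly cross it. The share of called genes that were higher went from 25.4% to 45.3%. A difference between the cell populations themselves was not tested.

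Between strains, genes differed in both blood populations. Sequence variants under single probes may affect some genes but were argued against as the whole cause, since 76.5% of the entries of another probe in a comparison (26 of 34), or 18 of 23 distinct probes, moved the same way by at least 50% of the called log2 change. This covers few genes: 236 of 289 calls had no other probe, and another 21 entries were dim in the higher group and left out, of which 6 followed, or 58.2% of 55 with both. Trpv4, B3galnt1, Slc27a2 and Hbe1 were among the genes with no other probe, so a variant was not tested for them. The row of the slide cannot be told apart from the strain, because 0 of 2 rows held both. The genetic difference between the strains stays open as a biological explanation, untested.

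For the fit over the 3 strata, 2 of 100 splits (of 108 possible) gave at least as many calls, the real one with 18 included. That share was below the level set. It cannot exclude chance, because most splits put the 2 arrays of a group on opposite sides. These arrays may be technical copies rather than different animals. Only splits that keep each pair together are comparable with the real one, and the others of that kind gave 0, 0 and 44 calls. The highest other split gave 44 and swapped the RT1B labels in glomeruli alone, which may point to a structure of the samples, but what raised that count was not tested. Across all genes the changes in glomeruli and in WKY and LEW blood correlated positively (0.28 and 0.18), so opposite directions hold only for part of the genes, such as the B cell list.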

How the results depend on the processing

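Counts of called genes by comparison moved beyond the ratio set for a stable count in the cases given for the settings named next; the cause was not tested. With the other background correction they were 0 for RT1B in WKY blood, 56 for strain in RT1B+, 48 for strain in RT1Blow, 1619 for tissue in RT1B+, 11 for RT1B between tissues and 8 for the 3 strata. With quantile normalization they were 29 for RT1B in WKY blood, 75 for RT1B in glomeruli, 4 for RT1B between strains, 29 for RT1B between tissues and 10 for the 3 strata. With no filter on dim probes they were 0 for RT1B in WKY blood, 0 for RT1B in LEW blood, 17 for RT1B in glomeruli, 67 for strain in RT1B+, 85 for strain in RT1Blow, 954 for tissue in RT1Blow and 6 for the 3 strata. With the stricter filter they were 0 for RT1B in WKY blood, 212 for RT1B in glomeruli, 85 for strain in RT1Blow, 4316 for macrophage, 8 for RT1B between tissues and 10 for the 3 strata. With the series matrix values they were 2 for RT1B in WKY blood, 0 for RT1B in LEW blood, 28 for RT1B in glomeruli, 331 for strain in RT1Blow and 4 for the 3 strata. With the compared arrays alone they were 0 for RT1B in WKY blood, 5 for RT1B in LEW blood, 0 for RT1B in glomeruli, 2 for strain in RT1B+, 477 for strain in RT1Blow, 687 for tissue in RT1B+, 17 for tissue in RT1Blow, 1743 for pan T and 3 for RT1B between tissues. With 1 slide alone they were 0 for RT1B in WKY blood, 0 for RT1B in LEW blood, 6 for RT1B in glomeruli, 289 for strain in RT1B+ and 309 for strain in RT1Blow. With the mean of all probes they were 20 for RT1B in LEW blood. With a trended and robust variance they were 20 for RT1B in LEW blood, 284 for RT1B in glomeruli and 30 for the 3 strata. With pair means they were 2 for the 3 strata. With the strata of slide 1 they were 60 for the 3 strata. Leaving out 1 array, whose group then holds a lone array assumed to vary like the others, stayed within that ratio for pan T and macrophage and gave 0 to 48 for RT1B in WKY blood, 0 to 16 for RT1B in LEW blood, 9 to 669 for RT1B in glomeruli, 18 to 177 for strain in RT1B+, 12 to 71 for strain in RT1Blow, 1026 to 2225 for tissue in RT1B+, 299 to 928 for tissue in RT1Blow, 2344 to 2918 for pan T, 5556 to 7056 for macrophage, 0 to 3 for RT1B between strains, 7 to 39 for RT1B between tissues and 0 to 43 for the 3 strata. No named gene turned direction under any alternative run. The camera direction of 2 lists that were not called turned: granule genes for tissue in RT1B+ with the series matrix values (median -0.06) and chemokine receptors for macrophage with the other background correction (median 0.10). Named genes kept their side of the threshold in 133 cases and lost the call in 15 with quantile normalization, in 448 and 239 with 1 array left out. With an estimated correlation 51 list calls were lost and 19 list results kept their side. No paired analysis was possible because the labels carry no replicate numbers that pair arrays. Signal was well above background in 57.3% to 68.6% of gene spots by array, and dimmer spots enter means and fold changes too, because a gene needed such signal in 1 group alone.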

Other observations

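The arrays of the blood RT1B+ groups stood apart from the others in 1 respect: for 4 of 16 arrays the most similar array across genes was not the other array of the group, and all 4 were blood RT1B+ arrays. The 2 WKY ones were closest to WKY blood RT1Blow replicate 2 (correlations across genes of 0.986 and 0.990, against 0.979 with each other), and genes are not independent replicates. The 2 arrays of each group differed by 1.54 to 3.28 times the spread that the replicate spots on an array would give. The RT1B+ against RT1Blow changes correlated across genes at 0.52 between WKY and LEW blood, 0.28 between WKY blood and glomeruli, and 0.18 between LEW blood and glomeruli; no array is shared between these contrasts.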
